A study of Mus musculus with 10 samples.

How the data were processed

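RNA from embryonic mouse limb buds was labelled with biotin and hybridised to Affymetrix arrays, 1 sample per array, per the labels' protocols. The deposited table holds 45101 probe sets in 10 arrays as linear intensity values. The submitters' processing notes name GCOS version 1.3. The summarization model, the scaling target and the detection calls are not given in the sources used here. The authors' intensity values were already on a common scale when deposited: the 2% trimmed means of the 10 arrays lay between 276 and 289, a spread of 4.76%, which was under the limit of 10% set for adding a normalization, so none was added. From 2 to 6 values per array were exactly 0. A compressed or offset summarization would understate the changes of dim genes, and without detection calls the distance of a dim probe set from background is unknown.

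Intensities below 1 were set to 1 and log2 was taken. The 64 control probe sets were left out, and probe sets with a mean log2 value over all 10 arrays at or above the median of all probe sets were tested (22519, with a mean corresponding to a signal of at least 151). The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend), with Benjamini-Hochberg adjustment at 0.05. The platform annotation gave 34945 probe sets 1 gene symbol, 932 several and 9160 none, and only those with 1 symbol were named. Gene identifiers of 34741 probe sets were found in the RefSeq gene table of assembly GRCm38.p6, which left 0 symbols to update and was used only for names and for the order of neighbouring genes. No genome build applies to the array values, so no coordinates are given. Each of 11601 genes was represented by its brightest tested probe set, with a probe set marked as shared between transcripts used only where there was no other. Of the 246 genes called in the 8-array comparison, 127 had several tested probe sets, and in 16 at least 1 of them had the opposite sign.

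The comparison of the 10 arrays as labelled, the gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. The rule named every Dicer1 probe set, the 12 largest rises and the 12 largest falls among called genes whose mutant arrays all lay on one side of all wild type arrays, and of each list up to 4 called members or, where none was called, up to 2 with the smallest p. As the comparison as labelled called no gene, the rule was applied to the 8 arrays left without the pair numbered 2, a comparison chosen after seeing the data, because the Dicer1 signal of each array of that pair went against its label. Hmga2, Hoxd8, Col2a1 and Sox9 were named after their values were seen. A shift of a list against all other genes was tested with camera at a preset correlation of 0.01 between genes, adjusted over 32 lists with at least 3 measured genes of 35 fixed. Measured members of a list are those past the filter, such as 16 of 28 cartilage and 9 of 20 white blood cell genes on the array. Camera with an estimated correlation called 0 lists in either comparison, and 0 in the 8 arrays with the replicate number as a block. The rotation test fry, which asks whether the genes of a list move on balance 1 way, called 0 lists, and 11 lists in the 8 arrays had members that changed in either direction by its mixed test. With the replicate number as a block, camera at the preset correlation called 8 lists in the 8 arrays and fry called 3. Dicer1 was also compared with an exact two-sided permutation test on its signals.

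Both groups carry the numbers 1 to 5, and no label says what a number marks. Deviations of same-numbered arrays from their group means correlated in the 10 arrays for every number but 2. Each array numbered 2 lay with the other group, which by itself sets their deviations against each other. The correlation therefore cannot show whether these arrays are paired. The numbers were not taken to pair all 10, although Xist and Eif2s3y signals matched within each number. Without the pair numbered 2 the correlations were 0.55, 0.55, 0.71 and 0.32 for numbers 1, 3, 4 and 5. The highest with an array of another number were 0.54, 0.54, 0.52 and 0.52. Only number 4 stood clearly above that and number 5 stood below it, so these values do not establish a pairing by number. The replicate block and the pairs below rest on the numbers as given. No array repeated the values of another. The first principal component (37.7% of the variance) separated numbers 1, 2 and 3 from 4 and 5, and values within each side are given for pairs 1 and 3 and for pairs 4 and 5.

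Alternatives were quantile normalization, centring on array medians, offsets of 16 and 64 before log2, no filter or a filter at the 70th percentile, no intensity trend, array weights, the replicate number as a block, the mean of all probe sets of a gene, and leaving out each array in turn. A planned test of microRNA seed matches in 3′ untranslated regions was not run, since no genome sequence was used here. The fitting code was tested on simulated data made from the real means with 200 changed probe sets among 22519. With 4 arrays per group it recovered 61.0% of the 1.5-fold and 91.7% of the 2-fold changes with 2.95% false calls. With 5 per group it recovered 76.0% and 93.7%, with 5.98% false calls. The simulated noise was independent between probe sets, with a spread taken from the 8 arrays without the pair numbered 2. The runs with 5 per group lacked that pair and the structure between numbers. They do not measure the power of the 10 arrays as labelled. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.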

Results

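Gene expression was measured in limb buds of mouse embryos from a cross between parents carrying floxed Dicer alleles, 1 of the parents also carrying the prxcre driver, a Cre recombinase transgene active in limb bud mesenchyme. Dicer, encoded by Dicer1, is the RNase that cuts precursor hairpins into mature microRNAs. The series asks which genes change when Dicer is removed from limb mesenchyme. It holds 10 Affymetrix arrays, 5 labelled wild type and 5 labelled Dicer mutant, numbered 1 to 5 in each group. Whether embryos heterozygous for the deleted allele are among those labelled wild type is not given in the sources used here, so every difference below is between the labelled groups only. Neither the embryonic stage nor the use of forelimbs or hindlimbs is given in the sources used here. The labels do not state whether an array holds 1 embryo or several, so p-values measure the spread between these samples. Median signals lay between 145.9 and 152.8 in all 10 arrays, and the number of arrays limits the precision.

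Dicer1 was lower in the Dicer mutant array than in the wild type array of the same number in 4 of the 5 pairs, and higher in the pair numbered 2. Probe set 1427941_at had signals of 425, 372, 390 and 706 in wild type 1, 3, 4 and 5, against 226, 221, 215 and 205 in Dicer mutant 1, 3, 4 and 5. The array labelled wild type 2 had 233, close to the other mutant arrays, and the array labelled Dicer mutant 2 had 360, close to the wild type arrays. Probe set 1460571_at gave the same picture, with 551 in the array labelled wild type 2 and 774 in the array labelled Dicer mutant 2, where the other wild type arrays had 707 to 940 and the other mutant arrays 506 to 555. The signal of the targeted gene went against the label of both arrays numbered 2. Every direction below is that of the labels as given. Where either probe set lies relative to the deleted part of the gene is not given in the sources used here.

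**Figure D1:**
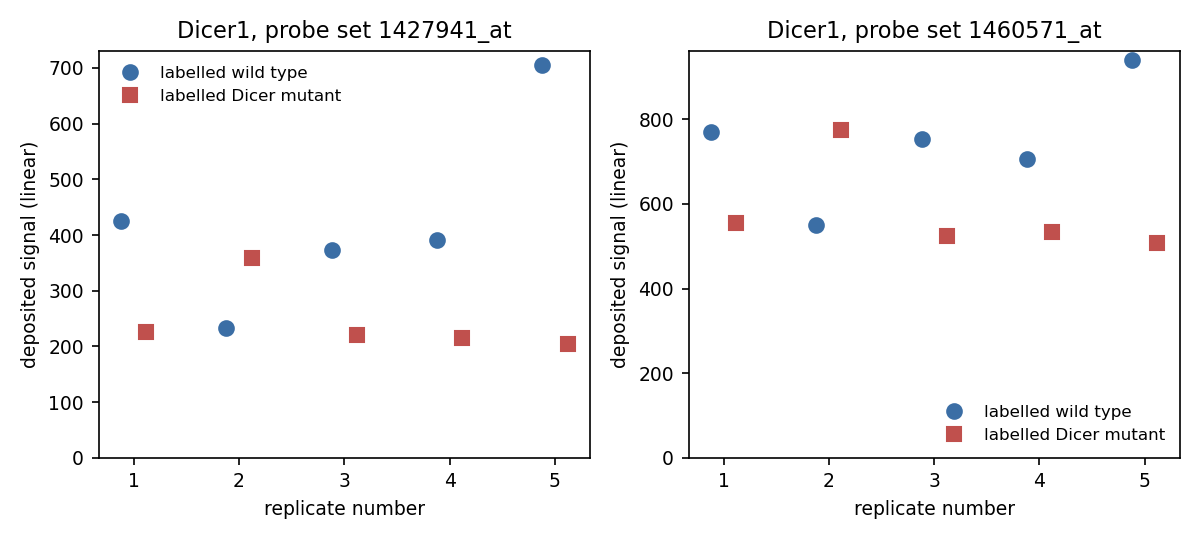
Deposited linear signal of the 2 Dicer1 probe sets in each array, by replicate number, with circles for arrays labelled wild type and squares for arrays labelled Dicer mutant. In pairs 1, 3, 4 and 5 the circle lies above the square, and in pair 2 the square (360 and 774) lies above the circle (233 and 551).

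With all 10 arrays as labelled, Dicer1 had a log2 fold change of -0.74 (SE 0.25, n = 5 per group; exact two-sided permutation p = 0.0159) at 1427941_at and -0.36 (SE 0.15; exact p = 0.0952) at 1460571_at, and limma's Benjamini-Hochberg adjusted p was 1.00 for both. No gene passed the test between the groups as labelled. Limma called 0 of 22519 probe sets at an adjusted p below 0.05, and 632 (2.81%) had an unadjusted p below 0.05. Since Dicer1 went against the label in both arrays numbered 2, these 0 calls do not show that Dicer loss leaves genes unchanged.  Known let-7 targets stood higher than other genes in the mutant arrays (median log2 fold change 0.083 over 16 genes, camera adjusted p = 5.24e-05), as did cell cycle genes (0.042 over 27 genes, adjusted p = 0.0134). Neither call held with an estimated correlation between genes (adjusted p = 0.787 for both). The cell cycle call was also lost without wild type 4, wild type 5, Dicer mutant 3 or Dicer mutant 5, with medians of 0.025, 0.024, 0.017 and 0.025, and the median turned to -0.0022 (adjusted p = 0.553) without both arrays numbered 5. Without wild type 2 or Dicer mutant 2 it stood at 0.071 and 0.082. The let-7 call held without each single array, at medians of 0.042 (without Dicer mutant 3), 0.045 (wild type 4), 0.055 (Dicer mutant 1), 0.14 (wild type 2) and 0.15 (Dicer mutant 2) where it moved most.

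Because both arrays numbered 2 went against their labels at the targeted gene, the comparison was repeated without them. That choice was made after seeing the data, so the fall of Dicer1 itself in the remaining 8 arrays is not independent of it, and no p-value from these 8 arrays is corrected for the choice. In those 8 arrays the mutant limb buds had higher levels of Prtg, Igdcc3, Trim71 and Lcor and lower levels of Rprm and Ddt, each in 4 of 4 pairs. Prtg, which encodes the cell surface protein protogenin, rose 2.80-fold (log2 fold change 1.49, SE 0.10, n = 4 per group, limma adjusted p = 0.000436). Its signal averaged 116 in the wild type and 324 in the mutant arrays, as geometric means. The wild type level lay under the filter cut of 151, at an unknown distance from background, so the size of this fold is uncertain. Trim71, an RNA-binding ubiquitin ligase and a classic let-7 target, rose 2.70-fold (1.43, SE 0.13, adjusted p = 0.00118). Rprm, which encodes the p53-induced cell cycle inhibitor reprimo, was the gene with the largest fall, 2.77-fold (-1.47, SE 0.19, adjusted p = 0.00821). Dicer1 was 2.11-fold lower at 1427941_at (-1.08, SE 0.18, adjusted p = 0.0272) and 1.49-fold lower at 1460571_at (-0.57, SE 0.098, adjusted p = 0.0282). An exact two-sided permutation test gave p = 0.0286 for each, the smallest value that 4 against 4 arrays allow.

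Across all genes, 378 of 22519 probe sets were called in the 8 arrays, 209 higher and 169 lower in the mutant arrays, and 2865 had an unadjusted p below 0.05. Of 11601 genes represented by 1 probe set each, 126 were higher and 120 were lower. Rises were larger than falls: 67 genes rose and 26 fell by more than 1.5-fold, and 11 rose and 1 fell by more than 2-fold. In all 246 called genes the 4 mutant arrays lay on one side of the 4 wild type arrays, which the call itself makes likely, so it is no separate support. Such a separation was seen in 10.3% of all tested genes, where chance gives 2.86% on average over divisions. Genes do not vary independently and the 8 arrays were chosen by Dicer1, so this excess cannot exclude chance. The pair numbered 2, which took no part in this fit, had the opposite sign for 245 of the 246 genes and the same sign for 1. In the 8 arrays the deviations of same-numbered arrays correlated, but only for number 4 clearly more than those of arrays with different numbers. With the replicate number as a block 1219 probe sets were called, 541 higher and 678 lower, including all 378. These came from 746 genes, 293 higher and 453 lower, with 11 rises and 2 falls of more than 2-fold.

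Other large rises covered several kinds of protein. Igdcc3, an immunoglobulin superfamily receptor related to protogenin, rose by 1.36 on the log2 scale (SE 0.17), and Lcor, a ligand-dependent nuclear receptor corepressor, by 1.23 (SE 0.079). The signal of Lcor averaged 389 in the wild type and 909 in the mutant arrays, as geometric means, and all 3 of its tested probe sets were called. Ankrd13c rose by 1.19, Pdzd2 by 1.11, Chic1 by 1.11, and the ubiquitin ligase adaptor gene Kbtbd8 by 1.07. The integrin gene Itgb8 rose by 1.06, Phtf2 by 1.05, Greb1l by 1.04 and the tyrosine phosphatase gene Ptpn4 by 1.00. Not every tested probe set of these genes was called: 1 of 3 was for Igdcc3 and Ankrd13c, 2 of 3 for Chic1, and 1 of 2 for Pdzd2, Phtf2 and Greb1l. The other Greb1l probe set had the opposite sign. Kbtbd8 and Itgb8, like Prtg, had wild type means (124 and 133) under the filter cut of 151 and passed it through their higher arrays. Falls after Rprm were smaller. Ddt, which encodes D-dopachrome tautomerase, had a log2 fold change of -0.94 (SE 0.092), the zinc finger gene Zfp560 -0.93, Lrrc17 -0.84, A930005H10Rik -0.81, and Nicn1 and Rundc3b -0.80 each. Smim14 stood at -0.74, Bex2 at -0.72, Iftap at -0.71, the prostaglandin reductase gene Ptgr1 at -0.71 and Chmp2b, a member of the ESCRT-III membrane-remodelling complex, at -0.68. Lrrc17 had 1 of 2 tested probe sets called, and its other probe set had the opposite sign. Smim14 had 2 of 3 called.

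**Figure D2:**
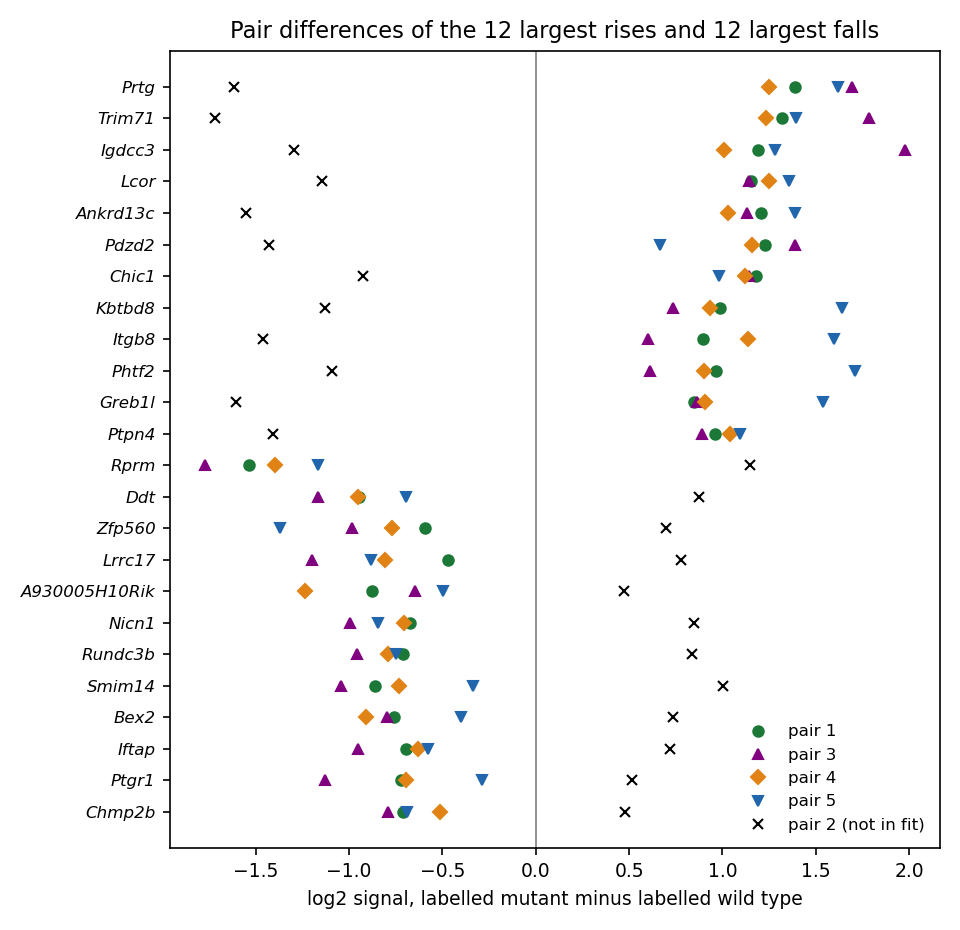
Difference in log2 signal between the array labelled Dicer mutant and the array labelled wild type of each replicate number, for the 12 genes with the largest rise and the 12 with the largest fall in the 8 arrays. Coloured markers are pairs 1, 3, 4 and 5, and crosses are pair 2, which was not in the fit: for Prtg the pairs stand at 1.39, 1.69, 1.25 and 1.62 and pair 2 at -1.62.

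The 378 calls of the 8 arrays became 110, 93 and 142 without wild type 1, 3 or 4, and 136, 103, 97 and 109 without Dicer mutant 1, 3, 4 or 5. Without wild type 5 they became 745. The share of calls that were higher in the mutant arrays, 55.3% in the 8 arrays, was 69.7% to 81.6% in the first 7 of these refits and 42.3% without wild type 5, so the balance of rises and falls depends on single arrays. Of the 38 genes named by the fixed rule, 18 kept their call without each of the 8 arrays in turn: Prtg, Trim71, Igdcc3, Lcor, Ankrd13c, Pdzd2, Chic1, Greb1l, Ptpn4, Tnrc6a, Bcl2l11, Hoxa9, Rprm, Ddt, Nicn1, Rundc3b, Bex2 and Chmp2b. The other 20 lost it in 3 to 7 of the 8 refits, with an adjusted p of up to 0.147 and no change of sign. Among them, Igf2bp1, Hoxa7, Col11a1, Chst11, Sall4, Gap43 and Jun lost it in 7 refits each. E2f5, Bmpr1b, Bcl2 and Plk2 lost it in 6 each. Dicer1 lost its call at both probe sets without wild type 1 or Dicer mutant 1, 3, 4 or 5, and at 1460571_at also without wild type 3, with an adjusted p of up to 0.0881 and 0.0949 and values of -1.11 to -1.05 and -0.60 to -0.55. Pairs 1 and 3 alone gave 812 calls and pairs 4 and 5 alone 0.

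Known let-7 targets stood higher as a list in the mutant arrays of the 8. The 16 measured members had a median log2 fold change of 0.22 (camera adjusted p = 2.56e-07; adjusted p = 0.330 with an estimated correlation), with 3 members called over all genes and 6 adjusted over the list alone. The called members were Trim71, Igf2bp1, an mRNA-binding protein of embryonic tissues (0.41, SE 0.079, adjusted p = 0.0385), and the transcription factor gene E2f5 (0.41, SE 0.077, adjusted p = 0.0349). Of these 3, only Trim71 kept its call without each array in turn. Hmga2, a well known let-7 target of the embryo, had a value of 0.084 (SE 0.062, adjusted p = 0.701), at mean signals of 4189 and 4439. The list was higher in 4 of 4 pairs, and its median was 0.14 without Dicer mutant 3 or without wild type 4. With the replicate number as a block, the rotation test fry, which called no list without it, called the let-7, microRNA processing and white blood cell lists (adjusted p = 0.0265 each). The block also raised the number of members called over all genes to 5 for let-7 targets, 2 for the Hox targets, 3 for targets of the miR-17 to miR-92 cluster, 3 for cartilage, 2 for tendon and connective tissue, 7 for BMP signalling and 2 for white blood cells. Adjusted over the list alone it gave 10 cartilage, 8 tendon, 8 BMP and 3 cell cycle genes.

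Hox genes with known miR-196 or miR-10 sites also rose as a list (median 0.14 over 5 genes, camera adjusted p = 0.00985; adjusted p = 0.330 with an estimated correlation). Hoxa7 was called over all genes (0.42, SE 0.081, adjusted p = 0.0394), and 2 members passed adjusted over the list alone, the other being Hoxd8 (0.44, SE 0.15, adjusted p = 0.216 over all genes, 0.0244 with the block, and 0.0233 at 0.58 without wild type 5). Targets of the miR-17 to miR-92 cluster were not called as a list (median 0.12 over 13 genes, adjusted p = 0.0528), but were without wild type 3 (0.13, adjusted p = 0.0491), wild type 5 (0.11, adjusted p = 0.0331) or Dicer mutant 5 (0.15, adjusted p = 0.0401). With all 8 arrays 1 member was called over all genes and 3 adjusted over the list alone, 2 of them higher and 1 lower. The called member was Bcl2l11, the gene of the pro-apoptotic protein BIM, which rose by 0.87 (SE 0.097, adjusted p = 0.00441), with 3 of its 4 probe sets called. The list of microRNA processing and effector genes was called as higher (median 0.10 over 15 genes, adjusted p = 0.0219; adjusted p = 0.330 with an estimated correlation), although its members split: Tnrc6a, whose protein carries out silencing together with Argonaute, rose by 0.73 (SE 0.087, adjusted p = 0.00573), while Dicer1 fell. Both passed adjusted over the list alone too. The call of this list was lost without Dicer mutant 3 (0.081, adjusted p = 0.0504) or wild type 4 (0.088, adjusted p = 0.0589).

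Cartilage genes fell as a list in the mutant arrays, with a median of -0.26 over 16 measured members (camera adjusted p = 0.00236; adjusted p = 0.442 with an estimated correlation), and were lower in 4 of 4 pairs. The median was -0.15 without wild type 3, where the call held. The collagen gene Col11a1 (-0.58, SE 0.10, adjusted p = 0.0314) and the chondroitin sulfotransferase gene Chst11 (-0.37, SE 0.074, adjusted p = 0.0466) were called over all genes, and 3 members passed adjusted over the list alone. Col2a1, the main cartilage collagen, had a value of 0.083 (adjusted p = 0.968) and Sox9, the chondrocyte master regulator, -0.27 (adjusted p = 0.362). Tendon and loose connective tissue genes stood lower as a list (median -0.24 over 17 genes, adjusted p = 0.0442; adjusted p = 0.729 with an estimated correlation) with 0 members called over all genes and 0 adjusted over the list alone; the smallest p-values were those of Mkx (-0.31, adjusted p = 0.270) and Col3a1 (-0.33, adjusted p = 0.303). This call was lost without wild type 3 (-0.14, adjusted p = 0.300) or Dicer mutant 5 (-0.15, adjusted p = 0.241).

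BMP signalling genes were called as lower (median -0.10 over 19 genes, adjusted p = 0.0249; adjusted p = 0.457 with an estimated correlation). The receptor gene Bmpr1b, which acts in digit cartilage, fell by 0.53 (SE 0.088, adjusted p = 0.0260), and 6 members passed adjusted over the list alone, 5 of them lower and 1 higher. The call was lost without wild type 5 (-0.10, adjusted p = 0.183) or Dicer mutant 5 (-0.10, adjusted p = 0.0592), and the median was -0.21 without wild type 4. Cell cycle genes were called as higher by a small amount (median 0.11 over 27 genes, adjusted p = 0.00293; adjusted p = 0.394 with an estimated correlation), with 0 members called over all genes and 0 adjusted over the list alone. The median was 0.053 without wild type 5. Birc5 had -0.24 (adjusted p = 0.131) and Cdk1 0.14 (adjusted p = 0.196). Macrophage and other white blood cell markers, which come from cells outside the mesenchyme, were called as higher (median 0.15 over 9 genes, adjusted p = 0.00525; adjusted p = 0.330 with an estimated correlation), with 0 members called over all genes and 1 adjusted over the list alone. Their leading members were Ctss (0.43, adjusted p = 0.0773, with the block 0.0197) and Tyrobp (0.49, adjusted p = 0.223, with the block 0.0164).

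**Figure D3:**
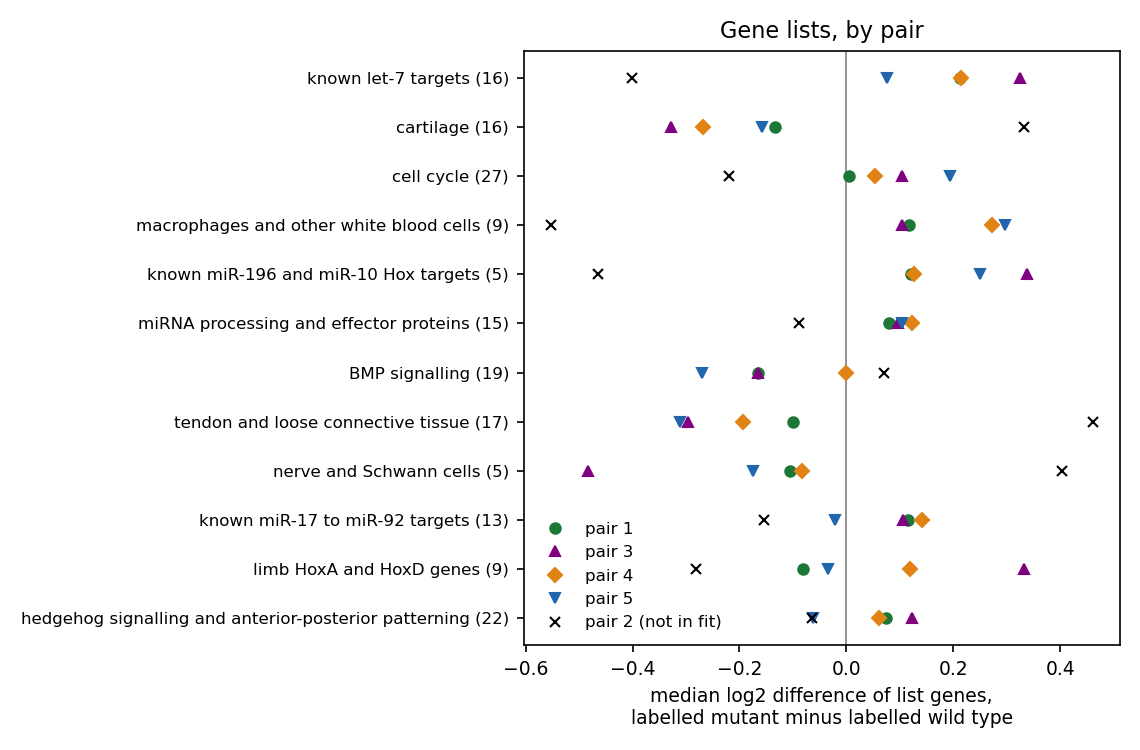
Median difference in log2 signal of the genes of each list between the array labelled Dicer mutant and the array labelled wild type of each replicate number, for the 12 lists with the smallest p in the 8 arrays (number of measured genes in brackets). Coloured markers are pairs 1, 3, 4 and 5 and crosses are pair 2, which was not in the fit: known let-7 targets stand at 0.21, 0.32, 0.21 and 0.075 and at -0.40 in pair 2, and cartilage genes at -0.13, -0.33, -0.27 and -0.16 and at 0.33 in pair 2.

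Single members of other lists were called while their lists were not, and the same members passed adjusted over the list alone. Hoxa9, expressed in the proximal limb bud, rose by 0.70 (SE 0.072, adjusted p = 0.00282), and the limb HoxA and HoxD genes as a list had a median of 0.10 (adjusted p = 0.105), called without wild type 1 (0.13, adjusted p = 0.0433) or wild type 5 (0.17, adjusted p = 0.0331). The zinc finger gene Sall4 rose by 0.83 (SE 0.16, adjusted p = 0.0408), in a hedgehog and anterior-posterior patterning list with a median of 0.085 (adjusted p = 0.447), called without wild type 5 (0.077, adjusted p = 0.0331). The survival gene Bcl2 fell by 0.66 (SE 0.12, adjusted p = 0.0313) while Bcl2l11 rose, and apoptosis regulators had a median of -0.0022 (adjusted p = 0.808). Plk2 fell by 0.67 (SE 0.12, adjusted p = 0.0341) among p53 targets (median -0.015, adjusted p = 0.808). The nerve growth cone gene Gap43 fell by 0.34 (SE 0.070, adjusted p = 0.0466) among nerve and Schwann cell genes (median -0.18 over 5 genes, adjusted p = 0.0503). This list was lower in 4 of 4 pairs and was called without wild type 1 (-0.20, adjusted p = 0.0406), wild type 5 (-0.31, adjusted p = 0.0331), Dicer mutant 1 (-0.23, adjusted p = 0.0475) or Dicer mutant 4 (-0.19, adjusted p = 0.0495). Jun fell by 0.53 (SE 0.10, adjusted p = 0.0410) among immediate early and heat shock genes, whose median was 0.0028 and mean -0.26 (adjusted p = 0.819). Adjusted over the list alone, 1 further member passed in the hedgehog list (lower) and 1 in the immediate early list (higher). With the block, 3 hedgehog genes, 2 p53 targets and 2 immediate early genes were called over all genes. Means and medians also differed in sign for p53 targets (mean 0.058) and apoptosis regulators (mean 0.011).

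The other lists tested had no called shift, and no called member without the block. Medians were 0.016 for host transcripts of microRNAs and -0.0034 for imprinted genes, -0.039 for limb bud mesenchyme and 0.0020 for hindlimb identity. They were -0.062 for the apical ectodermal ridge, 0.052 for FGF signalling targets, 0.0081 for proximal limb and retinoic acid genes, -0.052 for Wnt signalling and 0.013 for bone. The hindlimb list was dim: Pitx1 (signals of 152 to 178), Isl1 (140 to 177) and Hoxc10 (144 to 199) lay near the filter cut of 151. Its other members were Hoxc9 (201 to 238) and Tbx4 (137 to 320). Markers of other cell types had medians of -0.019 (skeletal muscle), -0.020 (endothelium), 0.072 (red blood cells) and 0.00093 (surface ectoderm). Cyclin-dependent kinase inhibitors stood at -0.061, interferon response genes at 0.020 and endoplasmic reticulum stress genes at -0.019. By the medians of single pairs the last list was higher in 4 of 4 pairs (mean 0.059, SE 0.026), still uncalled. The lowest adjusted p among these lists was 0.470. Adjusted over the list alone, 3 host transcripts passed, and 1 gene each of the imprinted, mesenchyme, hindlimb, FGF and endoplasmic reticulum stress lists. With the block, 3 host transcripts, 2 genes each of the mesenchyme and endoplasmic reticulum stress lists and 1 each of the imprinted, hindlimb, FGF, proximal limb, Wnt and ectoderm lists were called over all genes. The mean had the other sign for host transcripts (-0.020), imprinted genes (0.0090), proximal limb genes (-0.057), bone (-0.051), ectoderm (-0.014) and endoplasmic reticulum stress (0.063), and camera ranked the muscle list as higher at a median below 0. The hypoxia and glycolysis list stood at -0.23 (adjusted p = 0.470), at -0.45 (adjusted p = 0.0497) without wild type 3 and at 0.11 (adjusted p = 0.0331) without wild type 5, the array in which all 13 of its measured genes had their highest signal. Forelimb identity, dorsal-ventral patterning and sex-linked genes had fewer than 3 members past the filter and no list test: Tbx5 had -0.21 (adjusted p = 0.649), Hoxc5 0.16 (adjusted p = 0.476), Wnt7a 0.074 (adjusted p = 0.908), Lmx1b 0.038 (adjusted p = 0.977) and Xist -0.11 (adjusted p = 0.996).

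Of the members of these lists with the smallest p, several were uncalled without the replicate number as a block and called with it. Array weights, or pairs 1 and 3 alone, called most of these genes too. The retinoic acid synthesis gene Aldh1a2 had a log2 fold change of -1.03 (adjusted p = 0.294, with the block 0.00275), lower in 4 of 4 pairs, and the hindlimb gene Tbx4 0.58 (adjusted p = 0.157, with the block 0.00705), higher in 4 of 4. Dnajb9 had 0.54 (adjusted p = 0.0775, with the block 0.0132), Hspa5 0.22 (0.276, with the block 0.0296), and the Wnt inhibitor gene Dkk2 -0.71 (0.189, with the block 0.0200). Mest had 0.19 (0.0845, with the block 0.0204), Il17rd, an FGF feedback inhibitor, 0.47 (0.0931, with the block 0.0373), and Meox2 -0.41 (0.0758, with the block 0.0374). Krt14 had -0.39 (0.595, with the block 0.0435), Slit2, host of miR-218, -0.38 (0.0570, with the block 0.0447), and Pdgfra 0.20 (0.271, with the block 0.0480). Without wild type 5, and with no block, Mest (0.22, adjusted p = 0.0372), Il17rd (0.57, adjusted p = 0.0180) and Dnajb9 (0.62, adjusted p = 0.0373) were called too. Uncalled with or without the block were Erg (-0.46), Eng (0.060), Snrpn (-0.18), Hoxc10 (-0.054), Fgfr2 (-0.28), Dlx5 (-0.25), Fgf9 (-0.33), Crabp1 (-0.22), Rspo3 (-0.31) and Twist2 (-0.28). So were Mef2c (-0.23), Ckm (-0.15), Hbb-y (0.068), Hba-x (0.075), Krt17 (-0.18), Igfbp3 (-0.65), Cdkn1b (0.15), Ifit3 (-0.12), Irf1 (0.16), P4ha1 (-0.54) and Vegfa (-0.55). P4ha1 and Vegfa, of the hypoxia list, had their highest signal in wild type 5. Vegfa had 971 there, 225 to 264 in wild type 1, 3 and 4, and 186 to 281 in Dicer mutant 1, 3, 4 and 5, so its fall rests on that array.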

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

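The tests of the pair numbered 2, of wild type 5 and of the stage of collection were chosen after the result was seen, as was the comparison of 8 arrays itself, whereas the tests of other divisions of the arrays and of genes near Dicer1 were set before. Single arrays far from the other 4 of their group were found 32 times in 98 groups of 5 values. Chance gives about 1 in 20 groups of unselected values, but 76 of the groups, with 28 of the finds, are genes called in the 8 arrays without pair 2, which they separate; this favours distant arrays in that pair, so no chance value applies to them. The 18 groups of control probe sets had 2, against 0.9 by chance. Of the 32, 21 were the array labelled Dicer mutant 2, 9 the array labelled wild type 2 and 2 wild type 5.

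The distance of the array labelled Dicer mutant 2 from its nearest neighbour, as a share of the range of its group, was 0.938 for Ankrd13c, 0.920 for Bcl2l11, 0.721 for Chic1, 0.908 for Chmp2b, 0.789 for Col11a1, 0.766 for Ddt and 0.833 for Greb1l. It was 0.799 for Hoxa9, 0.831 for Igf2bp1, 0.852 for Lcor, 0.871 for Nicn1, 0.859 for Pdzd2, 0.875 for Plk2 and 0.781 for Prtg. It was 0.776 for Ptpn4, 0.729 for Rprm, 0.745 for Sall4, 0.750 for Smim14 and 0.797 for Trim71, and 0.829 and 0.783 for the Dicer1 probe sets 1427941_at and 1460571_at. For the array labelled wild type 2 the share was 0.809 for Ankrd13c, 0.770 for Ddt, 0.712 for Greb1l, 0.795 for Iftap, 0.907 for Lcor, 0.765 for Nicn1, 0.917 for Prtg, 0.781 for Ptpn4 and 0.763 for Rundc3b. Bcl2l11, for example, had a signal of 661 in the array labelled Dicer mutant 2 and 1360 to 1448 in the other mutant arrays. All of these genes but Dicer1 were named from the 8 arrays that leave out this pair, and Dicer1 was the reason to leave it out, so these distances are no separate evidence on the pair. In wild type 5 the share was 0.840 and 0.942 for a pair of control probe sets of 18S ribosomal RNA, with signals of 2270 against 317 to 435 and 1294 against 194 to 216 in the other wild type arrays.

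Both arrays numbered 2 lay on the other group's side. The second principal component (22.1% of the variance), which uses no labels, placed the array labelled wild type 2 at 14.9. Dicer mutant 1, 3, 4 and 5 lay at 10.3 to 16.1 on it. The array labelled Dicer mutant 2 was placed at -20.6, and wild type 1, 3, 4 and 5 lay at -14.1 to -8.1. On a scale set by the other 4 pairs over 200 probe sets, where 0 is their wild type mean and 1 their mutant mean, the array labelled wild type 2 scored 1.02 and the array labelled Dicer mutant 2 -0.10, a difference of -1.12, against 0.72 to 0.94 (mean 0.854, SD 0.093) in the other pairs when each was left out of the scale. A heterozygous or incompletely recombined embryo would lie between the groups and is argued against by that difference, and so is the sex of the embryos, since pair 4, with the same sex-linked signals as pair 2, had 0.876. An exchange of the labels of the 2 arrays may account for the pattern and stays open, as does the step at which it would have happened. With all 10 arrays the division as labelled called 0 probe sets, so all 100 divisions run, of 126 possible, called at least as many whatever the data, and this comparison says nothing about chance; the highest other called 2360 (numbers 1 and 3 with wild type 2 against the rest, which follows the structure of numbers) and the division with both arrays numbered 2 exchanged 1044.

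In the 8 arrays without pair 2, 2 of the 35 divisions gave as many calls as the real 378, so chance cannot be excluded by their share. The other was numbers 1 and 3 against 4 and 5, with 4932 calls, a structure of the samples that the replicate block removes (1219 calls); among the 8 divisions that part all pairs, the highest other had 0, though 8 are too few for a share under 0.05. Wild type 5 as the maker of the calls is argued against, since 95.8% of the called probe sets were still called without it. Alleles carried along with the floxed Dicer1 locus cannot be told apart from the loss of Dicer, because 4 of the 100 tested genes nearest to Dicer1 were called (4.00%, 95% exact interval 1.10% to 9.93%, against 2.12% of all genes), too few to decide. The loss of Dicer that the design names may therefore be the cause and stays open beside linked alleles.

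Cartilage and connective tissue lists were called as lower in the 8 arrays by camera at its preset correlation only (adjusted p = 0.442 and 0.729 with an estimated one), the second was lost without wild type 3 or Dicer mutant 5 (medians of -0.14 and -0.15), and Col2a1 stood at 0.083. Mutant limb buds collected at an earlier stage could give that pattern, and would also lower muscle genes. The muscle list's change minus 0.5 times that of the cartilage list was 0.0842 (SE 0.086, n = 4 pairs), within 2 standard errors of 0. Muscle stood higher in the mutant array in pairs 1, 4 and 5 (0.085, 0.10 and 0.030), against the stage explanation, and lower in pair 3 (-0.33, as cartilage did there), which carries most of the spread. With 4 pairs a difference in stage therefore cannot be told apart from an effect of Dicer loss.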

How the results depend on the processing

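The alternatives on the 8 arrays, and those leaving out a pair, were chosen after seeing the data. The 0 calls of limma in the 10 arrays as labelled stayed 0 under all 23 alternatives run (192 to 5172 at an unadjusted p below 0.05), and both Dicer1 probe sets kept their direction and stayed uncalled there; the replicate block gave 0 calls too (882 unadjusted), in arrays where not every number correlated (correlations of 0.43, -0.18, 0.27, 0.67 and 0.41 for numbers 1 to 5). For these arrays the count of called lists (2) was 5 with no filter, 5 without both arrays numbered 3, 4 without both numbered 5, 0 with an estimated correlation and 1 to 7 with single arrays left out; those gained in the most settings were microRNA processing (6), BMP (5) and hypoxia genes (5). The cell cycle list had 0.019 with array weights, -0.0022 without both arrays numbered 5 and 0.017 to 0.082 with single arrays left out, and with an estimated correlation both it (0.042) and let-7 targets (0.083) lost their call. The hypoxia list turned to 0.056 without both arrays numbered 5 and ranged from -0.32 to 0.067 with single arrays left out, the highest without wild type 5, and macrophage markers from -0.042 to 0.098, the highest without wild type 2. In the 8 arrays the 378 calls became 2612 with array weights (39.4% higher in the mutant arrays against 55.3%), 1219 with the replicate block (44.4%), 812 with pairs 1 and 3 only (39.3%), 0 with pairs 4 and 5 only, and 93 to 745 with single arrays left out (42.3% to 81.6% higher, the lowest without wild type 5); other settings gave 295 to 406. Scaling moved the share of higher calls by less than 10 percentage points (63.4% after quantile normalization). In the 8 arrays Dicer1 had -1.32 and -0.65 in pairs 4 and 5 only (adjusted p = 0.395 and 0.413), and with single arrays left out -1.18 to -0.87 and -0.63 to -0.49, lost calls lying between -1.11 and -1.05 and between -0.60 and -0.55. The count of called lists (8) was 9 after quantile normalization, 7 with no intensity trend, 7 to 12 with single arrays left out (the highest without wild type 5), 5 with the filter at the 70th percentile, 5 with array weights, 5 with pairs 1 and 3 only and 0 with an estimated correlation. Uncalled lists gained calls too: nerve and Schwann cell genes in 5 settings (-0.18 after quantile normalization and 4 single arrays left out), miR-17 to miR-92 targets in 3 and limb HoxA and HoxD genes in 2 (all single arrays), hedgehog genes in 2 (0.11 in pairs 1 and 3) and hypoxia genes in 3 (-0.69 in pairs 4 and 5). Lists that lost their call kept their direction: at the 70th percentile BMP (-0.12), tendon (-0.24) and macrophage genes (0.14); with no intensity trend tendon (-0.24); with array weights microRNA processing (0.075), BMP (-0.21) and cell cycle genes (0.042); in pairs 1 and 3 BMP (-0.15), tendon (-0.23), macrophage (0.10) and cell cycle genes (0.034); in pairs 4 and 5 the Hox targets (0.19). With an estimated correlation the 8 lists lost it at medians of 0.10 (microRNA processing), 0.22 (let-7), 0.14 (Hox targets), -0.10 (BMP), -0.26 (cartilage), -0.24 (tendon), 0.15 (macrophage) and 0.11 (cell cycle). With single arrays left out BMP ranged from -0.21 to -0.10, microRNA processing from 0.081 to 0.14, tendon from -0.31 to -0.14 and hypoxia from -0.45 to 0.11, the highest without wild type 5. The 38 named genes kept direction and call in 537 of 711 refits, lost the call in 174 and reversed in 0. In the 8 arrays the replicate block kept the calls of Dicer1, the 38 named genes and the 8 lists by camera (0 with an estimated correlation), and called 14 of 47 genes named as uncalled, where array weights called 17 and pairs 1 and 3 only 9; over all settings these 47 stayed uncalled in 835 of 881 refits, were called in the same direction in 46 and reversed in 0. Refits without arrays had fewer arrays to test with; the cause of the other changes was not tested. Without detection calls, how far dim probe sets stood over background is unknown. The seed-match test and its alternatives were not run.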

Other observations

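The tests on wild type 5 and of the numbers were chosen after the values were seen. All 13 measured hypoxia and glycolysis genes had their highest signal of the 10 arrays in wild type 5, with a median 3.66-fold above the mean of the other arrays. This array was the highest for 18.1% of all tested genes, a share that would give 2.35 of the 13. The glucose transporter gene Slc2a1 had 4984 there and 1006 to 1596 elsewhere, the mitophagy gene Bnip3 4333 against 572 to 1147, the growth factor gene Vegfa 971 against 186 to 281, and Ndrg1 970 against 197 to 226. The same array had the highest Dicer1 signal (706) and the high 18S controls. At 1 further 18S probe set it had 2008, but Dicer mutant 1 was also high there (1874), against 173 to 540 in the other arrays. The genes named here were picked after their values were seen.

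Samples also differed between replicate numbers. The median of the 27 muscle genes, each relative to its mean over the 8 arrays without pair 2, was lowest in the pair numbered 5, at -0.20 and -0.25 on the log2 scale against -0.013 to 0.68 in the other arrays. Actc1 there had signals of 761 and 762 against 1562 to 3921 in the other arrays, and Myog 186 and 217 against 362 to 675. Not every member was lowest there: Ckm had 280 and 301, against 204 in Dicer mutant 1. Shh, the signal of the posterior limb bud, was highest in the wild type array of that pair (412, with 393 in the mutant) and lowest in the array labelled Dicer mutant 2 (83.7). Gdf5 and Lum had their highest signals in the array labelled Dicer mutant 2, at 506 and 995. Xist was high in both arrays numbered 1, 3 and 5 (1545 to 2412) and low in both numbered 2 and 4 (65.8 to 73.1), where the Y-linked gene Eif2s3y was high (389 to 615).

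A hypothesis set before the test was that neighbouring genes change together. In the 8 arrays 7 neighbouring pairs were called in the same direction, against a mean of 2.60 and an upper limit of 6 in 10000 shuffles (one-sided permutation p = 0.0140). They include Hoxa7 with Hoxa9, Epb41l5 with Ptpn4 and Ppp1r9a with Pon2, all higher, and Hddc2 with Tpd52l1, both lower. Pdzd2 with 6030458C11Rik and Col11a1 with A930005H10Rik may be parts of shared transcripts, which was not tested. With every gene named after a clone left out, an alternative chosen after seeing the pairs, 5 pairs stood against a mean of 2.50 and a limit of 6 (one-sided permutation p = 0.107), so the excess was not kept.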
